A study of Malus domestica with 6 samples.

How the data were processed

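Exocarp of 3 fully russeted and 3 fully waxy apple varieties was sampled in October 2012, per the labels. Slices of skin 5 mm wide were cut from the fruit and freed of flesh, RNA was extracted from 250 mg of tissue with a CTAB protocol and treated with DNase, and samples with an RNA integrity number under 8 were excluded, per the labels' protocols. Libraries were made from 3 µg of total RNA with a poly(A) TruSeq kit that does not mark strand, with 15 cycles of PCR, per the labels' protocols.

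The authors deposited 1 table of 1261 gene models, made with CLC Genomics Workbench 6.5 per the file headers. Aligner settings and the genome build are not given in the sources used here. The deposited counts were of 2 kinds for each library, total gene reads and unique gene reads, and the second were never above the first. Reads placed at more than 1 gene are part of the total only, so near-identical copies share reads there. Of the 1261 genes, 254 had under 50% unique reads over the 6 libraries, among them 11 of the 67 genes chosen by rule, and their values are uncertain to that extent. The authors also deposited RPKM values, which are total gene reads scaled by coding length and by the mapped reads of the library, and the mean of the 3 RPKM values of each phenotype. Their comparison of the phenotypes, Baggerley's test per the file headers, was deposited as a signed fold, a score that is negative where russeted exocarp is lower, and as its log2 with the sign. The deposited p-value and false discovery rate of that test come with each gene. The largest false discovery rate in the authors' deposited table was 0.2 and the smallest absolute log2 fold change was 1. For all 1260 genes with a p above 0, the rate equalled p times 6449 divided by its rank to within 0.5%, so the authors' adjustment ran over 6449 genes. Other genes were not analysed here. The deposited gene length, in another column, was a multiple of 3 in all 1261 genes, so it is a coding length (median 1065 bases). Each column was tied to its sample by the variety name in its header. Gene models carry apple identifiers and were named by the Arabidopsis match, symbol and description in the table, which 1052 genes have. Of the 1261 identifiers, 0 matched the RefSeq gene table at hand, so no coordinates are given.

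Because the table holds selected genes only, its column sums are not library depths. The mapped reads of each library were recovered from each gene's reads, length and RPKM, as the median over genes with at least 200 reads, and the estimates within a library differed by rounding only (11.31 M to 11.33 M in St Edmund's Pippin, for example). These totals came to 47.6 M reads in russeted and 36.7 M in waxy libraries. Listed genes held 4.71% to 5.26% of the russeted and 7.09% to 9.73% of the waxy mapped reads. The lowest count of a listed gene in a library was 1, so no fold rests on a value of 0, but some rest on few reads. SRF5 (MDP0000159806), among the 12 largest rises, had 2, 1 and 1 reads in AG94, AF42 and Gala. CER1 (MDP0000461409), which fell, had 5, 4 and 4 reads in the russeted varieties. PCR reads carried no molecular identifiers.

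Total gene reads were tested with edgeR 4.0.16 (quasi-likelihood, two-sided) in R 4.3.3, with the 6 varieties as replicates of 2 phenotypes and the mapped reads as library sizes. The low-count filter of edgeR left 1246 genes and removed 15. P values were adjusted by Benjamini and Hochberg over 6449 genes, the number the authors' adjustment ran over, and the threshold was 0.05. Whether further genes had been dropped before that adjustment is not known here, and counting them would make the adjusted p larger. The genes not listed have no edgeR p here and were taken to have a larger p than the listed ones; any with a smaller p would make the true adjusted p smaller than those printed. The standard error of a log2 fold change is the fold divided by the square root of the F statistic. The common biological coefficient of variation was 0.481. TMM factors, which assume that most genes do not differ, had been fixed before the data were examined; mapped reads were chosen after the table proved to hold only genes selected for a difference, and both are reported. The adjustment over 6449 genes was also chosen after seeing the data.

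The gene lists (26) were fixed before the data were examined, by words and Arabidopsis identifiers. For each, the share of members with a fold above 0 was compared with that of the other tested genes by Fisher's exact test, adjusted over the 26 lists, since unselected genes were not analysed here. This test takes genes as independent, so its p is too small where the members of a list or family vary together. Genes to be named were also fixed by rule: the 12 largest rises and 12 largest falls among described genes past the threshold whose phenotypes do not overlap, and for each list up to 2 risen and 2 fallen members with the smallest p. Other list members and genes outside the rule were named after their values were seen. Library similarity used log2(RPKM + 1) of all 1261 genes. No library was a near copy of another, and no 2 libraries correlated above 0.94. Alternatives were other scalings, filters, tests (DESeq2 1.42.0, limma 3.58.1 on log2 RPKM with pseudocounts of 0.1, 1 and 5), thresholds, read types, a replicate block and leaving out each variety. Besides the mapped reads, which took the place of TMM factors, the adjustment over listed genes, unique gene reads, DESeq2 with mapped reads, limma on log2(RPKM + 1) and the authors' rate were added after seeing the data. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 served for the other tests and the plots.

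The edgeR step was tested on simulated data, with counts drawn for the 1261 genes at the real means, library sizes and common dispersion and 200 changed genes. Of the 1248 simulated genes that passed the filter, it recovered 2.04% of genes changed by 1 on the log2 scale, 51.0% of those changed by 2, and 100% of those changed by 3 or 4, with 0 of 1051 unchanged genes called. In this simulation, changes of 1 on the log2 scale were therefore mostly not called. The simulated genes shared 1 dispersion and only 200 were changed, whereas the listed genes were selected for a difference. The adjusted p depends on how many genes change. Neither the recovery nor the 0 unchanged genes called can therefore be carried over to the real table.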

Results

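The outer skin (exocarp) of apple, Malus domestica, was profiled by RNA sequencing in 6 varieties. The 3 russeted varieties, St Edmund's Pippin, Reinette Parmentier and Patte de Loup, had a rough, corky skin over the whole fruit. The 3 waxy varieties, AG94, AF42 and Gala, had a smooth, wax-covered skin. Each variety gave 1 library, so the errors below reflect the spread between varieties of a phenotype (n = 3 per phenotype), and no variety had a replicate of its own. The SD of an RPKM mean is the gene's own. The SE and p of a log2 fold change rest on dispersions that edgeR shares in part over the tested genes. The deposited table held 1261 gene models that the authors had selected on these same libraries for a difference between the phenotypes, which means that the tests below describe selected genes and are not independent evidence. Mapped reads (M) were 11.3 in St Edmund's Pippin, 19.1 in Reinette Parmentier, 17.2 in Patte de Loup, 16.8 in AG94, 10.5 in AF42 and 9.44 in Gala. The median listed gene had between 54 reads (Gala) and 219 reads (Patte de Loup). Gene models are given by their table identifiers and by the symbol or description of their Arabidopsis match in the table. Their positions are not given, since no coordinates were used here.

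The comparison of russeted with waxy exocarp asked which genes differ between the corky and the smooth skins of these varieties. Since the phenotypes are different varieties, skin type cannot be told apart from any other difference between the 3 russeted and the 3 waxy ones. Of 11 tested suberin genes, whose products build the waterproof polymer of cork cell walls, 10 rose in the russeted varieties. Of 17 cutin and wax genes, whose products build the cuticle, 10 fell and 3 rose. The share of suberin genes above 0 was not shown to differ from that of the other listed genes (Fisher's exact test, adjusted p = 0.87). With 11 members, and 73.7% of the other listed genes above 0, this test could hardly show a difference. It also leaves out the size of the folds, whose median on the log2 scale was 3.28 for suberin genes and 1.19 for all tested genes. The omega-hydroxylase gene CYP86B1 (MDP0000306273) averaged 23.1 ± 11.8 RPKM (SD, n = 3) in russeted and 0.923 ± 1.09 RPKM in waxy exocarp, a 24.0-fold difference. The 3-ketoacyl-CoA synthase gene KCS10 (MDP0000235280), which acts in the elongation of cuticular lipids, averaged 2.17 ± 3.03 RPKM in russeted and 117 ± 41.7 RPKM in waxy exocarp, a 53.2-fold difference in the other direction. Many disease resistance genes and NAC transcription factor genes also rose in russeted exocarp. Of 1246 genes tested with edgeR's quasi-likelihood test, 239 rose and 116 fell in russeted exocarp at a Benjamini-Hochberg adjusted p under 0.05, so that 67.3% of these genes were higher. This direction depended on the scaling. With TMM factors computed on the listed genes, 44 genes rose and 296 fell (12.9% higher), and the median log2 fold change of the tested genes moved from 1.19 to 0.20. Changes below are relative to the mapped reads of each library, and the TMM counts are given beside the groups they alter.

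The counts also moved when single varieties were left out. Each such fit had fewer libraries, so a call lost here or below can reflect that as well as the variety left out. Without St Edmund's Pippin 153 genes rose and 67 fell, without Reinette Parmentier 135 rose and 73 fell, and without Patte de Loup 134 rose and 71 fell. Without Gala 159 rose and 101 fell. In the authors' deposited table, 933 genes had a higher and 328 a lower mean in russeted exocarp, and 317 higher and 136 lower genes had a false discovery rate under 0.05. The edgeR and authors' directions differed in 0 of the tested genes, and 164 of the 355 genes past the edgeR threshold also had a deposited false discovery rate under 0.05, while 191 did not. Of the 453 genes under 0.05 in the authors' deposited table, 288 were tested with edgeR and not past its threshold. The 3 russeted values lay wholly on one side of the 3 waxy values in 1104 of the 1261 genes (87.5%); chance gives 10% for genes not selected, whereas these were selected for a difference on the same libraries, so the count tests nothing.

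**Figure D1:**
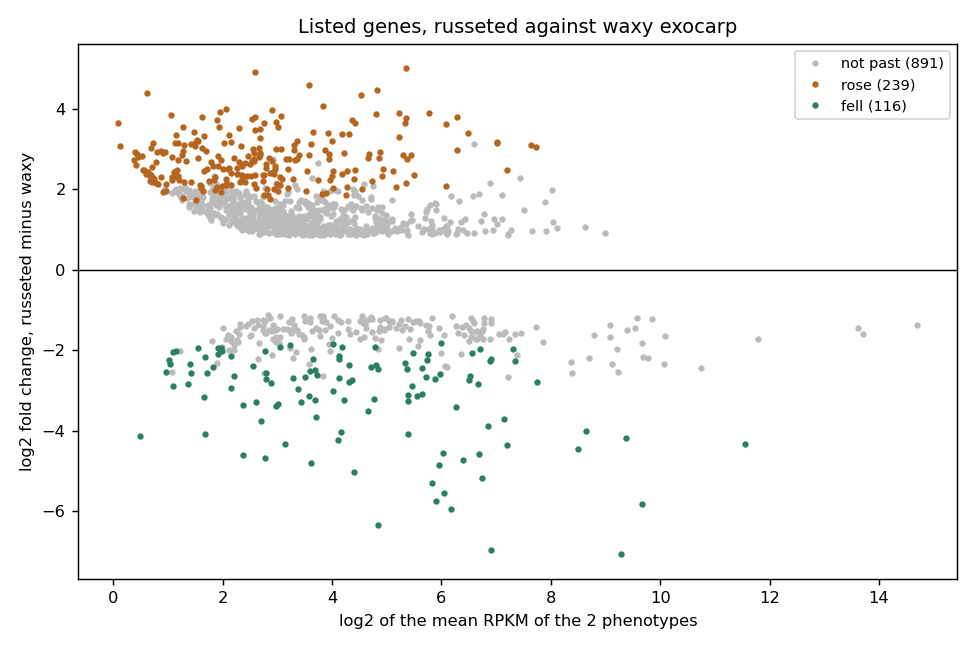
Each point is 1 of the 1246 tested genes, with the log2 of its mean RPKM on the x axis and its log2 fold change (russeted minus waxy, edgeR) on the y axis. Brown points are the 239 genes that rose in russeted exocarp, green points the 116 that fell and grey points those not past the threshold; the gap around 0 reflects the authors' selection.

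Libraries of a phenotype resembled each other more than libraries of different phenotypes across the listed genes, which were chosen for that difference. Pearson's r of log2(RPKM + 1) across genes was 0.84 to 0.88 between russeted varieties, 0.91 to 0.94 between waxy varieties, and 0.50 to 0.68 between phenotypes. Reinette Parmentier was the russeted variety nearest to the waxy ones, with r of 0.68 to AG94, 0.67 to AF42 and 0.64 to Gala. The first principal component held 75.4% of the variance and separated the phenotypes. The median SD of the log2 values was 0.48 within russeted and 0.45 within waxy varieties.

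Of the 11 suberin genes tested, 10 rose in russeted exocarp, 0 fell and 1 was not past the threshold. Their median log2 fold change was 3.28. Both copies of CYP86A1, which encodes the omega-hydroxylase of root suberin in Arabidopsis, rose, by 3.86 ± 0.85 (SE) on the log2 scale in MDP0000923760 and 3.28 ± 0.80 in MDP0000879217. CYP86B1 rose in its 2 copies as well, by 4.58 ± 0.77 (MDP0000306273, adjusted p = 0.00393) and 2.85 ± 0.58 (MDP0000234292, adjusted p = 0.0105). GPAT5 (MDP0000150502), an acyltransferase that makes suberin precursors, averaged 27.0 ± 16.8 RPKM in russeted and 1.57 ± 1.39 RPKM in waxy exocarp (log2 fold change 4.07 ± 0.70, adjusted p = 0.00481). The copies of the transcription factor MYB93 rose by 3.83 ± 0.73 (MDP0000320772) and 3.46 ± 0.72 (MDP0000228252). The other 3 risen members were 2 ABC-2 type transporter genes and an HXXXD-type acyltransferase gene, MDP0000312405, which averaged 137 ± 99.3 RPKM in russeted and 17.6 ± 8.74 RPKM in waxy exocarp. Only 15.5% of the reads of the transporter gene MDP0000241976 were unique to it. KCS2 (MDP0000625646), which is on the cutin and wax list too, had a log2 fold change of -1.61 ± 0.63 and was not past the threshold (adjusted p = 0.182). Folds were above 0 in 10 members and below 0 in 1, against 910 above and 325 below among the other tested genes (Fisher's exact test, two-sided, adjusted p = 0.87 over 26 lists). Adjusted over the list alone, 10 rose and 1 fell; this is not independent evidence, since the authors chose the genes on these samples. With TMM factors 3 members rose and 1 fell. The number that rose was 7 without Reinette Parmentier, without Patte de Loup or without AF42, and 8 without Gala. Among the calls lost was that of CYP86A1 MDP0000879217 (adjusted p = 0.0737 without Reinette Parmentier, 0.0562 without Patte de Loup and 0.0725 without AF42). The acyltransferase gene MDP0000312405 and the ABC-2 type gene MDP0000265619 were lost without Reinette Parmentier (adjusted p = 0.0757 and 0.0543), Patte de Loup (0.0551 and 0.145), AF42 (0.0673 for both) or Gala (0.0639 and 0.0901).

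Of the 17 cutin and wax genes tested, 10 fell in russeted exocarp, 3 rose and 4 were not past the threshold, with a median log2 fold change of -2.53. The falls were spread over the pathway. Among genes of fatty acid elongation, KCS10 had log2 fold changes of -5.73 ± 0.99 (SE, MDP0000235280) and -4.36 ± 0.77 (MDP0000134273), and KCS6, also named CER6 (MDP0000392495), averaged 8.29 ± 6.86 RPKM in russeted and 198 ± 69.6 RPKM in waxy exocarp (log2 fold change -4.57 ± 0.86, adjusted p = 0.00683). PAS2 and CER10, which act in the same elongation cycle, fell with log2 fold changes of -1.97 ± 0.56 (MDP0000337353) and -1.92 ± 0.51 (MDP0000062802). PAS2 lost its call without any 1 variety (adjusted p = 0.0629 without Gala to 0.132 without St Edmund's Pippin), and CER10 without any 1 but Gala (adjusted p = 0.057 without AG94 to 0.114 without St Edmund's Pippin). CER1 (MDP0000461409), needed for alkane formation, had a log2 fold change of -4.13 ± 0.65 (adjusted p = 0.00346). GPAT6 (MDP0000479163), the acyltransferase that makes cutin precursors, averaged 14.7 ± 8.71 RPKM in russeted and 215 ± 49.8 RPKM in waxy exocarp (log2 fold change -3.87 ± 0.68, adjusted p = 0.00505). The export transporter ABCG11 fell in both copies, with log2 fold changes of -4.84 ± 0.88 (MDP0000200335) and -4.60 ± 0.72 (MDP0000248808). CER3 (MDP0000165547) had a log2 fold change of -2.53 ± 0.79 and was not past the threshold (adjusted p = 0.0766). The 3 members that rose, and 1 that fell, were GDSL-type lipase genes, a family named for its motif that also acts outside the cuticle. Without Reinette Parmentier 1 member rose, and MDP0000146006 (adjusted p = 0.0616) and MDP0000136589 (0.0696) lost their calls. Only 26.6% of the reads of MDP0000146006 were unique to it. Its phenotypes overlapped, with 4.99 RPKM in St Edmund's Pippin and 5.73 RPKM in AG94. The gene matched to the symbol WIN1 (MDP0000250039) is described in the table as a HOPW1-1-interacting protein, not as a cuticle regulator, and had a log2 fold change of 0.91 ± 0.47 (adjusted p = 0.397).

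Cutin and wax genes were above 0 less often than the other listed genes, in 4 of 17 members (23.5%), against 916 above and 313 below 0 among the others (Fisher's exact test, two-sided, adjusted p = 0.000238). Adjusted over the list alone, 3 rose and 13 fell, and with TMM factors 0 rose and 13 fell. Waxy and russeted values of the fallen members did not overlap in any of the 10 genes, but the same held for 350 of all 355 genes past the threshold. In Reinette Parmentier the fallen members stood at a median of 8.44% of their waxy mean, against 2.34% in St Edmund's Pippin and 4.76% in Patte de Loup.

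**Figure D2:**
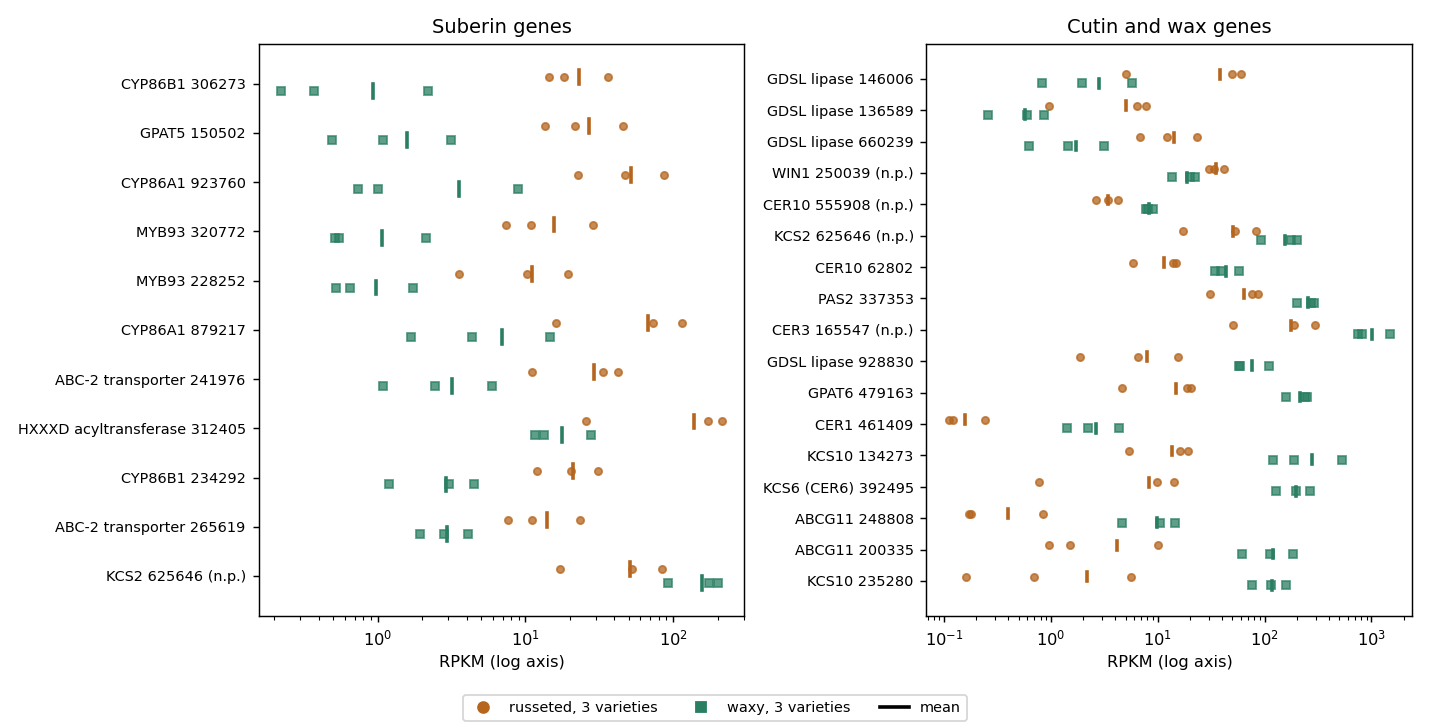
RPKM values (log axis) of the tested suberin genes (left) and cutin and wax genes (right), with the end of each gene's identifier; circles are the 3 russeted varieties, squares the 3 waxy varieties and bars the means, and n.p. marks genes not past the threshold. In 10 of 11 suberin genes the russeted mean lies above the waxy mean, and in 13 of 17 cutin and wax genes below it.

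Some single genes of lipid and triterpene metabolism outside this list were among the largest changes. Both WSD1-like O-acyltransferase genes in the table, a family of wax ester synthases, were among the 12 largest falls, with log2 fold changes of -5.55 ± 0.83 (MDP0000701887) and -5.01 ± 0.66 (MDP0000195926). A fatty acid hydroxylase gene, MDP0000477496, fell by 5.95 ± 1.10 on the log2 scale; 42.5% of its reads were unique to it. The triterpene list had 1 tested member, CYP716A1 (MDP0000440922), a P450 of the family that oxidises triterpenes. It fell from 374 ± 32.7 RPKM in waxy to 54.1 ± 27.9 RPKM in russeted exocarp (log2 fold change -2.79 ± 0.64, adjusted p = 0.0173), also adjusted over the list alone and with TMM factors. The call was lost without Reinette Parmentier (adjusted p = 0.0718) and without Patte de Loup (adjusted p = 0.0664), and a list of 1 gene cannot show a direction (Fisher's exact test, adjusted p = 0.87). A terpenoid cyclase gene, MDP0000207731, was among the 12 largest rises and averaged 70.3 ± 52.8 RPKM in russeted and 4.64 ± 2.87 RPKM in waxy exocarp. The 2 lipid transfer protein genes had log2 fold changes of 2.65 and 1.27 and were not past the threshold, though both rose adjusted over the list alone; with TMM factors 0 passed, and 1 rose without AG94.

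NAC transcription factors, a plant family that includes regulators of secondary walls, rose in 6 of 8 tested genes and fell in 0, with a median log2 fold change of 3.01. The 3 copies of NAC075 rose by 3.84 ± 0.65 (SE) on the log2 scale (MDP0000618650), 3.79 ± 0.61 (MDP0000723762) and 3.32 ± 0.60 (MDP0000124509). NAC038 (MDP0000232008) was the most abundant member, with 75.9 ± 38.8 RPKM in russeted and 5.58 ± 3.78 RPKM in waxy exocarp (adjusted p = 0.00393), and NAC058 and NAC073 completed the 6. Without Reinette Parmentier, Patte de Loup or Gala 4 NAC genes rose, and the NAC058 and NAC073 calls were both lost in each case. Among 15 tested MYB genes 7 rose, 3 fell and 5 were not past the threshold, and with TMM factors 2 rose and 3 fell, which turns the balance. The number that rose was 3 without Reinette Parmentier and 4 without Patte de Loup or without Gala, and the number that fell was 1 without St Edmund's Pippin or without Patte de Loup. MYB67 (MDP0000157506) rose by 3.63 ± 0.57 (adjusted p = 0.00346), with 9.79% of its reads unique to it, and MYB52 (MDP0000852158) by 3.00 ± 0.71 (adjusted p = 0.0199; 0.057 without St Edmund's Pippin and 0.0604 without Reinette Parmentier). MYB94 (MDP0000149535), an activator of wax genes in Arabidopsis, averaged 3.59 ± 2.26 RPKM in russeted and 33.7 ± 16.6 RPKM in waxy exocarp (log2 fold change -3.22 ± 0.64, adjusted p = 0.00856). MYB42 and MYB68 were the other 2 that fell; MYB42 lost its call without St Edmund's Pippin (adjusted p = 0.0606) or Patte de Loup (0.0582), and MYB68 (MDP0000812430) without any 1 variety (0.0572 without AG94 to 0.184 without Reinette Parmentier). Adjusted over the list alone, 8 NAC genes rose, and 10 MYB genes rose and 3 fell. With TMM factors 4 NAC genes rose and 0 fell. Of the WRKY genes 1 of 5 rose, WRKY65 (4 adjusted over the list alone), which was lost without St Edmund's Pippin (adjusted p = 0.0569) and without AF42 (adjusted p = 0.0631). The AP2 and ERF list had 1 riser among 3 tested genes, NGA1, which carries a B3 domain and is not an ethylene response factor (3 adjusted over the list alone); 0 rose without any 1 variety other than AG94. With TMM factors 0 genes of these 2 lists passed. None of these lists was shown to differ from the other listed genes in its share above 0 (Fisher's exact test, smallest adjusted p = 0.625). All 8 NAC, all 5 WRKY and all 3 AP2 and ERF genes were above 0. No higher share was possible, so these lists were too small for the test to show a difference.

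Genes of phenolic polymers went both ways. Of 9 tested phenylpropanoid and lignin genes, 4 rose, 2 fell and 3 were not past the threshold, and with TMM factors 1 rose and 2 fell, which turns the balance. All 4 that rose encode laccases, enzymes that couple phenolic units: LAC14 in MDP0000148967 (log2 fold change 3.78 ± 0.73) and MDP0000211955 (2.77 ± 0.53), and LAC15 in MDP0000202801 and MDP0000655646. The LAC14 copies shared most of their reads with other genes, with 40.1% and 42.3% unique. The 2 that fell encode cinnamyl alcohol dehydrogenases of monolignol synthesis, CAD9 (-3.33 ± 0.72) and CAD4 (-2.81 ± 0.70). The phenylpropanoid counts were 5 and 2 adjusted over the list alone, and 1 gene fell without St Edmund's Pippin, Reinette Parmentier, Patte de Loup or AG94, CAD9 being lost in the first case and CAD4 in the others. LAC15 was lost without Patte de Loup, AG94 or AF42 in MDP0000202801 and without St Edmund's Pippin in MDP0000655646. Of 3 peroxidase-list genes 2 rose, a peroxidase superfamily gene, MDP0000598572, by 3.66 ± 0.69 and the thioredoxin-dependent peroxidase gene TPX1 by 2.07 ± 0.57; all 3 rose adjusted over the list alone, and 1 with TMM factors. TPX1 was lost without Reinette Parmentier, Patte de Loup, AG94 or Gala, where 1 peroxidase-list gene rose.

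Cytochrome P450 genes rose in 7 and fell in 2 of 15 tests, with TMM factors in 1 and 3, which turns the balance. Without Patte de Loup 3 rose and 0 fell, without Reinette Parmentier 5 rose and 0 fell, and without St Edmund's Pippin 6 rose and 1 fell. Of the 7 risers 4 were the CYP86 genes of the suberin list. CYP707A3, which breaks down abscisic acid, and CYP716A1 were the 2 that fell, CYP707A3 losing its call without any 1 russeted variety (adjusted p = 0.0528 to 0.0641). P450 genes adjusted over the list alone rose in 9 cases and fell in 3. Among ABC transporters 2 of 10 rose, both suberin-list members, and 4 fell, the 2 copies of ABCG11 and the ABC-2 type genes MDP0000094058 (-4.54 ± 0.76) and MDP0000149064 (-4.07 ± 0.81). ABC transporter genes adjusted over the list alone rose in 5 cases and fell in 4, and with TMM factors 0 rose and 4 fell. The number that rose was 1 without Reinette Parmentier, Patte de Loup, AF42 or Gala.

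Few polysaccharide wall genes passed the threshold. Of 10 pectin genes 2 rose, GAUT6 (MDP0000195879, log2 fold change 2.83 ± 0.56) and a pectin acetylesterase gene, MDP0000756536 (2.86 ± 0.78), of whose reads 13.3% were unique. Of 5 wall-loosening genes 2 rose, the arabinogalactan gene FLA2 and the xyloglucan-modifying gene XTH22 (TCH4), and 0 of 5 cellulose and hemicellulose genes passed. Adjusted over the list alone, 8 pectin, 3 wall-loosening and 0 cellulose genes rose and 0 fell; with TMM factors 0 genes of these 3 lists passed, and the wall-loosening share above 0 went from over to under that of the other listed genes. Without any 1 russeted variety 1 pectin gene rose, GAUT6; the acetylesterase gene was also lost without AF42 or Gala. Of the wall-loosening genes 1 rose without St Edmund's Pippin, Reinette Parmentier, AG94 or Gala and 0 without Patte de Loup; XTH22 was lost in all 5 cases and FLA2 in the last (adjusted p = 0.0511).

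The cell division list had 3 risers among 9 tested genes, the histone gene HTA7, CYCP4;1 and the tubulin gene TUA2, and with TMM factors 0 rose and 1 fell. The cell division counts adjusted over the list alone were 8 and 1, and without AG94 1 rose and 1 fell and without Gala 1 rose. TUA2 lost its call without any 1 variety but St Edmund's Pippin (adjusted p = 0.0574 without Gala to 0.0956 without Patte de Loup), HTA7 without St Edmund's Pippin (0.16), AG94 (0.0552) or Gala (0.0705), and CYCP4;1 without Patte de Loup (0.0542). Of genes of hormone pathways, 1 SAUR-like gene rose among 7 auxin genes (MDP0000848515, log2 fold change 3.54 ± 0.58; 3 rose adjusted over the list alone), with TMM factors 1 rose and 1 fell, and without AF42 2 rose. The carotenoid-cleaving dioxygenase gene NCED4, also named CCD4, fell among 4 abscisic acid genes (MDP0000555220, -4.07 ± 0.71), and the other 3, all for protein phosphatases 2C, were not past the threshold, also when adjusted over the list alone. The share of this list above 0 was 75% and became 25% with TMM factors, which turns it to the lower side. EIN3 was the 1 ethylene-list gene, with a log2 fold change of 1.93 and an edgeR adjusted p of 0.0756; it rose adjusted over the list alone and without AG94, and not with TMM factors.

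Disease resistance genes formed the largest group on one side. Of the 56 pathogenesis-related and defence genes tested, 22 rose, 2 fell and 32 were not past the threshold, and 54 of 56 (96.4%) had a fold above 0, against 866 above and 324 below 0 among the other tested genes (Fisher's exact test, two-sided, adjusted p = 0.000238). Disease resistance proteins make up 52 of the 56 members by description, and these include all 22 that rose. Fisher's test takes the members as independent, so its p is too small if such related genes vary together. Most of these 22 are of the TIR-NBS-LRR receptor class that senses pathogens, and their levels were low. MDP0000529326, among the 12 largest rises, averaged 7.26 ± 0.39 RPKM in russeted and 0.46 ± 0.308 RPKM in waxy exocarp (log2 fold change 3.91 ± 0.63, adjusted p = 0.00346), with 33.7% of its reads unique. MDP0000458484 rose by 2.93 ± 0.55 (adjusted p = 0.00667). An RPP1-type gene, MDP0000827008, went the other way, from 46.5 ± 18.2 RPKM in waxy to 4.02 ± 4.99 RPKM in russeted exocarp, and so did a gene of the pathogenesis-related 1 superfamily, MDP0000629887 (log2 fold change -3.21 ± 0.61). Adjusted over the list alone, 48 rose and 2 fell. With TMM factors 3 rose and 2 fell, and 92.9% of the members were above 0. The number that rose was 10 without St Edmund's Pippin, 12 without Reinette Parmentier, 9 without Patte de Loup, 13 without AG94, 11 without AF42 and 10 without Gala. The RPP1-type gene lost its call without St Edmund's Pippin (adjusted p = 0.0856), where 1 member fell.

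**Figure D3:**
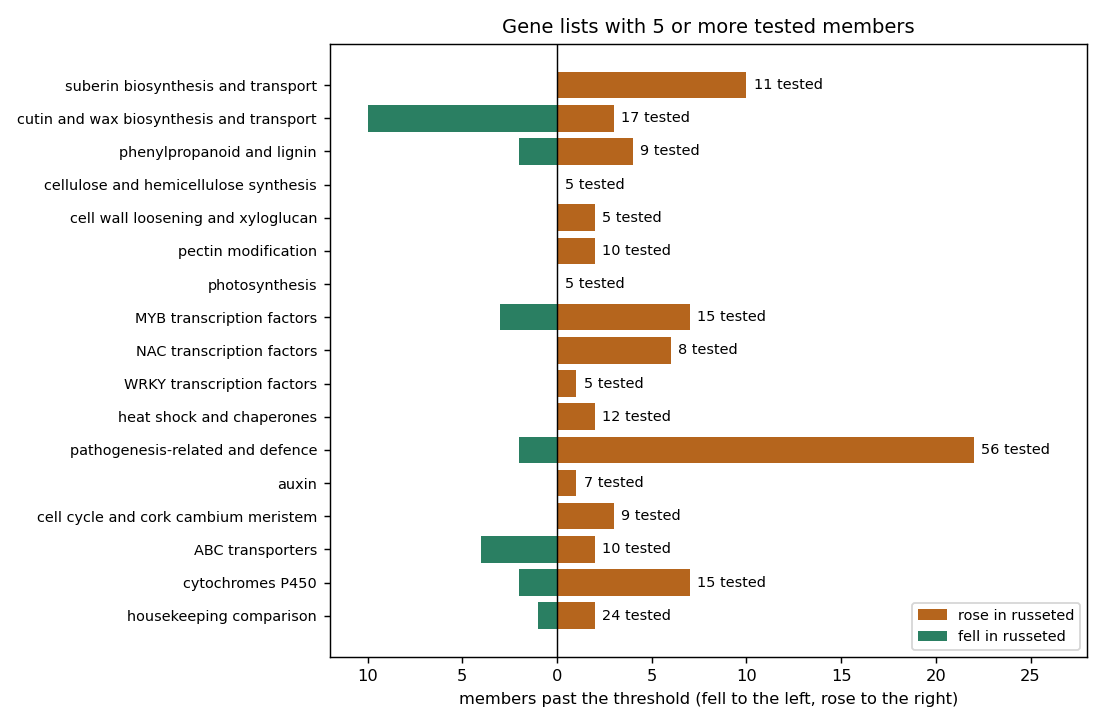
Bars give the number of members of each gene list with 5 or more tested members that rose (brown, to the right) or fell (green, to the left) in russeted exocarp, with the number tested beside each bar. Suberin genes rose in 10 of 11 tests and cutin and wax genes fell in 10 of 17. Members of the pathogenesis-related and defence list rose in 22 of 56, all 22 described as disease resistance proteins. With TMM factors these became 3, 13 and 3.

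Markers of other tissues that a peel could hold differed between the phenotypes in a few genes. Of 4 phloem protein genes tested as vascular markers, 2 rose, PP2-A9 by 3.20 ± 0.75 (SE) on the log2 scale and PP2-A1 by 3.12 ± 0.82, and the same 2 adjusted over the list alone, while with TMM factors 0 passed. No vascular marker passed with edgeR without Reinette Parmentier (adjusted p = 0.0622 for PP2-A9 and 0.124 for PP2-A1) or without Patte de Loup (0.0618 and 0.0926), and 1 rose without AG94 or without Gala. Of 4 fruit flesh markers 1 rose, sucrose synthase SUS4 (MDP0000250070), which averaged 76.5 ± 48.6 RPKM in russeted and 10.7 ± 1.43 RPKM in waxy exocarp. Another 2 flesh-list members are invertase or pectin methylesterase inhibitor genes that matched the list by name only. All 4 flesh-list genes rose adjusted over the list alone, and 0 with TMM factors. These shifts went the same way as those of the suberin and defence genes. Of the 24 housekeeping genes in the table, all selected for a difference, 22 had a fold above 0. A ribosomal protein gene, MDP0000156653, and UBC2 rose and a 60S acidic ribosomal protein gene, MDP0000177670, fell; with TMM factors 0 rose and 2 fell, which turns the balance, and adjusted over the list alone 7 rose and 1 fell. Of housekeeping genes 0 rose without St Edmund's Pippin and 1 without AG94, AF42 or Gala; MDP0000156653 was lost without St Edmund's Pippin, Patte de Loup, AG94 or AF42, and UBC2 without St Edmund's Pippin, AG94 or Gala.

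Heat shock and chaperone genes rose in 2 of 12 tests and fell in 0, and with TMM factors 0 rose and 3 fell, which turns the balance; adjusted over the list alone 7 rose and 3 fell. The number that rose was 1 without St Edmund's Pippin, Patte de Loup or AG94 and 5 without AF42. No flavonoid gene (2 tested) and no photosynthesis gene (5 tested) passed with edgeR. When adjusted over the list alone, 1 flavonoid gene rose and 1 fell, and 1 photosynthesis gene rose and 2 fell. With TMM factors 1 gene of each of these 2 lists fell, as it did without Reinette Parmentier, and 1 flavonoid gene rose without AG94. At an unadjusted p under 0.05, 1006 of the 1246 tested genes would have passed.

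The largest changes of all lay partly outside the lists. The largest rise was that of TIC55-II (MDP0000150374), a chloroplast protein import gene, from 2.50 ± 3.74 RPKM in waxy to 79.3 ± 35.8 RPKM in russeted exocarp (log2 fold change 5.00 ± 1.00, adjusted p = 0.00906), but only 8.06% of its reads were unique to it. It was followed by an HXXXD-type acyltransferase gene, MDP0000253113 (4.91 ± 0.70), CYP86B1, a wound-responsive gene, MDP0000769493 (4.45 ± 0.74, 22.1% unique reads), the receptor kinase gene SRF5 (4.38 ± 0.68) and a cupredoxin gene, MDP0000175065 (4.34 ± 0.70). The largest fall was that of IMS1 (MDP0000123747), matched to a 2-isopropylmalate synthase of leucine synthesis, from 1231 ± 837 RPKM in waxy to 9.17 ± 9.78 RPKM in russeted exocarp (log2 fold change -7.07 ± 1.11, adjusted p = 0.00346). Next came an NmrA-like gene, MDP0000751143 (-6.95 ± 1.01), and another gene of that family, MDP0000466251, fell as well (-5.17 ± 0.75). The RING-finger gene RHA2B (MDP0000612469) fell from 1604 ± 910 RPKM to 28.7 ± 42.1 RPKM (adjusted p = 0.0106; 0.0591 without Reinette Parmentier).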

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

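TMM factors were the planned scaling. Mapped reads, the adjustment over 6449 genes, and the alternatives with listed genes only, unique gene reads, DESeq2 with mapped reads, limma on log2(RPKM + 1) and the authors' rate were chosen after seeing the data. The direction of the 67 genes chosen by rule was the same under every alternative that tested them. These genes were chosen on the same data as past the threshold, so this agreement was largely built in and is weak support. The direction of the cutin and wax, suberin and defence lists relative to the other listed genes was also the same under every alternative. The stricter filter, with at least 10 reads in each library and a mean of at least 50, tested only 26 of the 67 genes. The counts of genes depended on the scaling. The numbers that rose and fell, 239 and 116 with edgeR and mapped reads, became 44 and 296 with TMM factors, 43 and 296 with median-of-ratios factors, 111 and 322 with DESeq2 and its own factors, 71 and 219 with quantile-normalized values and 60 and 316 with median-centred values. These settings centre genes that were selected for a difference. Other settings kept most calls on the higher side: 53 and 37 at a threshold of 0.01, 597 and 290 adjusted over the listed genes, 547 and 266 with DESeq2 and mapped reads, 382 and 224 with limma and a pseudocount of 5, and 797 and 307 for phenotypes that do not overlap, with no test. The stricter filter gave 142 genes that rose, with 887 genes tested. Leaving out 1 variety gave 134 to 194 genes that rose and 67 to 105 that fell, with fewer libraries per fit, and 6 to 17 of the 67 genes lost their call. More of the 67 lost it in other settings: 22 with TMM factors, 22 with median-of-ratios factors, 28 at a threshold of 0.01 and 35 by the authors' rate. Relative to the other listed genes, some lists changed side, none of them past the threshold in any setting, and the cause was not tested. The share above 0 became 60.0% for phenylpropanoid, 58.3% for heat shock and 25% for abscisic acid genes with DESeq2 and its own factors, and 58.3% and 25% for the last 2 with median-of-ratios factors. It became 70.0% for heat shock genes with the stricter filter, 60.0% for cellulose genes with quantile normalization, and with TMM factors 60.0% for wall-loosening, 58.3% for heat shock and 25% for abscisic acid genes. With the numbers 1 to 3 of the sample titles as a replicate block, 209 genes rose and 110 fell. Same-numbered varieties did not deviate together (correlations of -0.088, -0.021 and -0.095), so the numbers pair nothing. A filter on mean RPKM of 1 removed no gene and says nothing.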

Other observations

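Some gene groups outside the fixed lists, chosen after their values were seen, held several genes past the threshold. Of 6 tested terpenoid cyclase genes, which form triterpene skeletons, 5 rose in russeted exocarp, by 3.52 to 3.90 on the log2 scale. They include both copies of CAMS1, camelliol C synthase, of which MDP0000553490 averaged 9.03 ± 6.72 RPKM in russeted and 0.783 ± 0.238 RPKM in waxy exocarp. The exception, MDP0000227287, was the most abundant, with 258 ± 128 RPKM in russeted and 822 ± 219 RPKM in waxy exocarp (log2 fold change -1.67 ± 0.71, edgeR adjusted p = 0.236). With TMM factors 4 cyclase genes rose and 0 fell. Of 9 histone genes 4 rose and 0 fell, 1 with TMM factors and 2 without Patte de Loup or without AG94. In a test of protein families the share above 0 was not shown to differ from that of the other listed genes for the cyclase domain PF00432 (Fisher's exact test, adjusted p = 1) or the histone domain PF00125 (adjusted p = 0.414). All 7 tested genes with PF00125 were above 0, so that family was too small for this test to show a difference. All 4 tested UCP015417 genes rose, by 2.34 to 3.97, but 1 with TMM factors and 2 without St Edmund's Pippin, AG94 or Gala. Both cupredoxin genes were among the 12 largest rises.

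Other groups went both ways. Of 96 genes with the word kinase in their description 14 rose and 8 fell. With TMM factors 3 rose and 24 fell, which turns the balance. It also turned for UDP-glycosyltransferases (4 rose and 1 fell of 13, with TMM factors 0 and 6). The same held for glutathione S-transferases (3 and 1 of 6, with TMM factors 0 and 1). Kinase genes rose and fell in 11 and 2 cases without St Edmund's Pippin, 7 and 4 without Reinette Parmentier, 10 and 5 without Patte de Loup, and 8 and 8 without Gala. Glycosyltransferases rose and fell in 1 and 1 cases without St Edmund's Pippin, 2 and 1 without Reinette Parmentier, Patte de Loup or Gala, and 2 and 2 without AF42. No transferase of the glutathione group fell with edgeR without Reinette Parmentier, Patte de Loup or AF42. Of 8 alpha/beta-hydrolase genes 2 rose and 3 fell (0 and 5 with TMM factors, 0 and 1 without Reinette Parmentier, 0 and 3 without AG94), and of 2 Ovate family genes 1 rose and 1 fell (0 and 1 with TMM factors). HXXXD-type acyltransferases, a family that esterifies hydroxycinnamoyl and other acyl groups, split. Of 11 genes with that description 7 fell, with log2 fold changes of -4.73 to -2.21, and 2 rose, the suberin-list gene MDP0000312405 and MDP0000253113, by 2.97 and 4.91. With TMM factors 1 rose and 7 fell; 1 rose and 3 fell without Reinette Parmentier, 1 rose without Patte de Loup, AF42 or Gala, and 3 rose without AG94. In the exploratory test of 31 protein families with at least 6 tested members, 4 differed from the other listed genes in their share above 0. They were NB-ARC (32 of 32 above 0, Fisher's exact test, adjusted p = 0.00348), the HXXXD transferase family (3 of 12, adjusted p = 0.00823), short-chain dehydrogenases (1 of 7, adjusted p = 0.0175) and NUDIX hydrolases (1 of 6, adjusted p = 0.0437). SVB (MDP0000179031), which carries a DUF538 domain of unknown function, was the most abundant gene that fell, from 5688 ± 2481 RPKM in waxy to 282 ± 101 RPKM in russeted exocarp. PSY, which encodes the first enzyme of carotenoid synthesis, fell by 2.27 ± 0.55 on the log2 scale, a call lost without any 1 russeted variety (adjusted p = 0.0566 to 0.106) and without Gala (0.0501).

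The tests of the first 2 patterns below, mixed tissue and the surplus of risen genes, were chosen after the results were seen; the splits of the libraries and the tests on defence genes were not. The first pattern is that genes lower in russeted exocarp were less low in Reinette Parmentier. Of 116 fallen genes, 58 had their highest russeted value in this variety, 24 in St Edmund's Pippin and 34 in Patte de Loup. A strip of waxy-type skin in this sample may account for it, and would lift every gene to at least the share of waxy tissue, 8.44% by the fallen cutin and wax genes. In Reinette Parmentier 7.76% of the fallen genes lay below a level of 0.5 times that share, but the same measure gave 8.62% in St Edmund's Pippin and 19.0% in Patte de Loup with their own shares, so this measure does not separate a mixture from a weaker fall in this variety. IMS1, RHA2B and the NmrA-like gene MDP0000751143, picked from the 12 largest falls, stood there at 1.24%, 0.936% and 0.558% of their lowest waxy value, under the 8.44% that a mixture with skin like that of these 3 waxy varieties would leave; the level of these genes in waxy-type skin of Reinette Parmentier itself was not measured, so a mixture with such skin stays open.

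The second pattern is that risen genes outnumber fallen ones, 239 to 116. A uniform background of reads in the russeted libraries would put a floor under every gene, but the 5th percentile of RPKM was at most 2.01 in these libraries, against a median rise of 8.02 RPKM. Abundant waxy transcripts would need to take up most of the waxy reads, and the 328 listed genes with a lower mean in russeted exocarp held at most 8.86% of them. All listed genes together held only 7.09% to 9.73% of the waxy mapped reads. The genes that held the rest were not analysed, so abundant waxy transcripts among them stay open. The scaling stays open: with TMM factors 12.9% of the genes past the threshold were higher, but those factors centre genes selected for a difference, so neither scaling is shown to be right. Of the 10 ways to split the 6 libraries into groups of 3, 1 gave as many genes, the real one with 355, and the highest of the others gave 0; 10 splits are too few for a share under 0.05, and the genes had been selected for the real grouping.

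The last pattern is the near uniform direction of the defence list, 54 of 56 above 0. By description 52 of its members are disease resistance proteins, 51 of them above 0. Reads shared between paralogs could move such a family together, but with unique gene reads 96.4% of the members were above 0 (Fisher's exact test, adjusted p = 0.000163). Low abundance could as well, since 86.1% of the tested genes in the least abundant of 3 equal sets were above 0. In 10000 random lists matched on mean RPKM the upper end of the central 95% was 91.1% above 0, below the 96.4% of the defence list. These lists and Fisher's test take genes as independent. If resistance genes vary together between varieties, that range is too narrow and the Fisher p too small. Whether they do was not tested, so low abundance stays open. Differences between varieties in the resistance genes they carry, and how closely these match the reference, were not tested and stay open beside an effect of the phenotype.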
